A study of Mus musculus with 6 samples.

How the data were processed

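Gene expression was measured in heart ventricles of mouse embryos at stage E11.5 on Affymetrix arrays of the mouse 430 2.0 design, a 1-colour array on which a gene is represented by 1 or more probe sets. Per the labels, 3 arrays carried RNA of embryos with a targeted deletion of skNAC and 3 carried RNA of wild-type littermates on the 129SvEv background, and 500 ng of total RNA per sample was amplified and biotin-labelled. Arrays are named here by genotype and the number in their titles: knockout 1, 26 and 66, and wild-type 13, 23 and 57. The genotypes share no number, so no arrays were paired, and the labels do not say which embryos shared a litter or whether an array held 1 heart or several. The p-values therefore measure the spread between these samples, whatever its source.

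The values analysed are probe set intensities on a linear scale, which the authors made with GCOS and MAS5, per the submitters' processing notes. Software versions, scaling settings and detection calls are not given in the sources used here. In the deposited intensity table every array had a 2% trimmed mean of 250, the mark of per-array scaling, and medians ran from 92.0 in knockout 1 to 113.9 in knockout 66. Such scaling makes signals relative to the rest of the same array, so a change in total RNA per cell leaves no trace. A 1-colour array gives no counts, and the number of arrays limits the precision: the median standard error of a log2 difference was 0.21 over probe sets.

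Of 45101 probe sets, 64 were array controls. The platform annotation gave 1 gene symbol for 34958 probe sets and several for 932, and it listed no gene for 9211. Of those with 1 symbol, 34754 matched a gene of the mouse RefSeq table by Entrez identifier, and 0 symbols needed updating. No genome build is tied to the values, so no coordinates are given.

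Intensities were transformed as log2(intensity + 16). Fold changes are on that scale and understate the change of dim genes. Probe sets were kept when their mean over the 6 arrays lay above the median of all non-control probe sets, an intensity of 95.2, which left 22518. Each was fitted in limma 3.58.1 under R 4.3.3 with lmFit and eBayes with a trend, two-sided, and p-values were adjusted by the Benjamini-Hochberg method with calls at 0.05. Each gene was represented by its brightest kept probe set with 1 symbol, giving 11661 genes adjusted among themselves. Where other probe sets of a named gene disagreed in sign, this is stated.

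Before the data were examined, 27 gene lists were fixed, covering muscle structure, heart development, growth, metabolism, stress, matrix and the cell types and tissues that could accompany a ventricle. The 25 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way or in either direction. The median of each list was also ranked among 10000 random lists of the same size and matched signal, a description added after the data were seen. The rule for naming genes was fixed with the lists, before the data were examined. It took the targeted gene and its partner Smyd1, the 12 genes in each direction with an adjusted p under 0.05, filled up by smallest p among genes whose arrays did not overlap between genotypes, and up to 4 members per list by smallest p. Genes without a symbol, predicted genes and RIKEN clones were passed over. Single values were compared by a two-sided exact permutation test over the 20 assignments of 6 arrays, whose smallest possible p is 0.1.

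The fit was tested on simulated data with 22518 probe sets. Noise was drawn independently for each probe set, from the spread typical of its signal level and of each array. Spread particular to single probe sets and correlation between genes were left out. The simulation may therefore overstate recovery, and it does not show how often lists of correlated genes are called. It recovered 32% of probe sets changed by 0.5 on the log2 scale, 76% of those changed by 1, 82% at 2 and 72% at 3. There were 3 false calls, and a simulated list shifted by 0.3 was called. A strong decrease can take a probe set below the filter, and such probe sets counted as not recovered. Alternatives tried were pseudocounts of 1 and 64, no filter and a stricter filter at the 70th percentile, quantile normalization, centring on array medians, eBayes without a trend or with robust estimation, array quality weights, no probe sets ending in _x_at or _s_at, the mean of a gene's probe sets, an adjusted p threshold of 0.1, each array left out in turn and, added after the sex-linked signals were seen, no genes on chromosomes X and Y. Figures were drawn with Matplotlib 3.10.9 under Python 3.11.15.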

Results

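Ventricles of mouse embryos lacking skNAC, the long muscle-specific transcript of the Naca gene, were compared with ventricles of wild-type littermates at stage E11.5, shortly before the lethality that the labels place by E12.5. The question was which transcripts differ in the knockout heart. Each genotype had 3 arrays. Array medians lay between 92.0 and 113.9, at a common trimmed mean of 250, and signals reached 31202. Values below are mean MAS5 signals ± SD of 3 arrays per genotype, and log2 differences are knockout minus wild-type ± SE.

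No difference between genotypes was detectable in the targeted gene. Naca had 2 probe sets, and whether either reads the muscle-specific part is not given in the sources used here. The brighter one read 9047, 9034 and 8595 in knockout 1, 26 and 66 and 8385, 8566 and 8286 in wild-type 13, 23 and 57. Its log2 difference was 0.08 ± 0.08 with a 95% interval from -0.10 to 0.26, and it became -0.015 after quantile normalization. The other gave 0.08 ± 0.11. Smyd1, the muscle methyltransferase that binds skNAC, read 1027 ± 192 in knockout and 1099 ± 7.78 in wild-type on its brightest probe set, a difference of -0.11 ± 0.14. Its other 4 kept probe sets lay between -0.41 and 0.18. The lowest of them read 783 in knockout and 1053 in wild-type, with a 95% interval from -0.78 to -0.04. Its p in limma was 0.0319 unadjusted and 0.975 adjusted.

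The 12 genes of smallest p among those lower in all knockout arrays included myoglobin (Mb), the oxygen-binding protein of heart muscle. It read 605 ± 239 in knockout and 1431 ± 204 in wild-type, a log2 difference of -1.30 ± 0.26. The background potassium channel gene Kcnk3 read 164 ± 42.6 against 371 ± 21.8 (-1.13 ± 0.20), and Eef1a2, the translation elongation factor of muscle and neurons, read 619 ± 108 against 1022 ± 58.9 (-0.72 ± 0.14). All 3 knockout arrays lay below all 3 wild-type arrays for each of these, yet none passed the adjustment over all genes, and a second, dimmer Mb probe set pointed the other way, at 147 against 77.5.

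The remaining low genes of the 12 named in that direction were of mixed function. Ccn2, a matrix-associated growth regulator, read 563 ± 60.1 against 918 ± 175 (-0.68 ± 0.16), and the splicing regulator Rbfox1 read 595 ± 36.7 against 956 ± 199 (-0.65 ± 0.16). Clec4g, a C-type lectin, read 67.7 ± 39.0 against 238 ± 57.3, with a knockout mean below the 95.2 at which probe sets were kept. Ppbp, a platelet chemokine, gave -0.56 ± 0.14, and Pcyox1, a prenylcysteine oxidase, -0.69 ± 0.15. Fbxo10 (77.8 against 204, also below that level in knockout), Tob2 (-0.54), Map9 (-0.60) and the flap endonuclease Fen1 (-0.54) completed the set. Fen1, Tob2 and Pcyox1 rested on probe sets ending in _x_at or _s_at. Without such probe sets their differences were 0.30, -0.11 and -0.24. Rbfox1 had only a probe set of that kind.

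In the opposite direction, Krt8, a keratin of simple epithelia including the epicardium, read 1257 ± 315 in knockout and 706 ± 94.2 in wild-type (0.80 ± 0.18), and its other 2 kept probe sets were also higher, by 0.72 and 0.25. Cct3, a subunit of the chaperonin that folds actin and tubulin, read 11450 ± 727 against 8313 ± 515 (0.46 ± 0.09), and Wdr1, an actin-disassembly factor, read 2422 ± 337 against 1550 ± 122 (0.63 ± 0.13). The ubiquitin-like modifier Ufm1 gave 0.78 ± 0.16 and the lipid droplet gene Bscl2 0.72 ± 0.16. Trpc4ap (0.74), Thtpa (0.61), the histone methyltransferase gene Setd1a (0.76), F8a (1.38), the tRNA methyltransferase gene Trmt61a (1.15), the hedgehog ligand Dhh (1.24) and Unc93b1 (1.44) were the others. The last 4 had wild-type means between 59.6 and 111, near or below the 95.2 at which probe sets were kept. Thtpa had only a probe set ending in _s_at.

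None of these 24 genes is reported as changed. In limma, 0 of 22518 probe sets and 0 of 11661 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.892 over probe sets and 0.642 over genes. At an unadjusted p under 0.05 there were 1083 probe sets, 493 higher and 590 lower in knockout, where chance alone gives 1126. Among genes there were 547, where chance gives 583. The genotypes did not overlap in 10.9% of genes, against 10% by chance. With array quality weights, which gave knockout 66 a weight of 0.33 and knockout 26 a weight of 2.53, 8 genes passed: Cct3, Krt8, Ufm1 and Wdr1 higher, and Eef1a2, Kcnk3, Mb and Pcyox1 lower. Of the 24, 11 had more than 1 kept probe set, and 8 of those had at least 1 of opposite sign (Cct3, F8a, Fen1, Map9, Mb, Setd1a, Ufm1 and Wdr1).

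**Figure D1:**
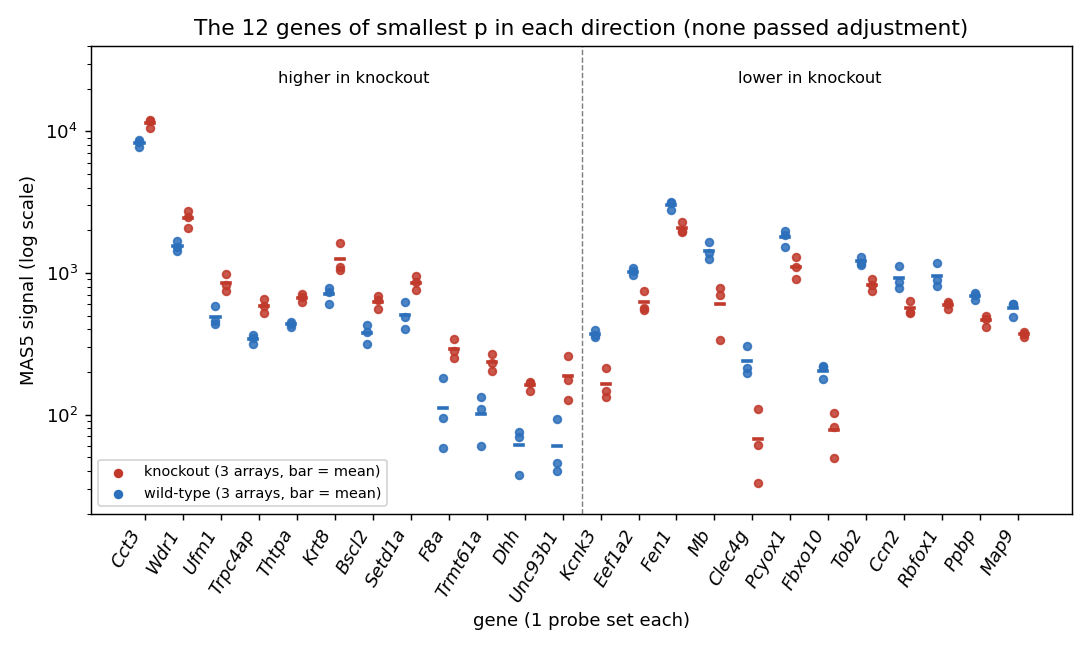
MAS5 signal on a log axis for the 12 genes of smallest p in each direction, with 1 probe set per gene, a point for each of 3 knockout (red) and 3 wild-type (blue) arrays and a bar at the mean. The points of the genotypes do not overlap for any of the 24 genes, by the rule that chose them, and the smallest adjusted p was 0.642.

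The arrays did not group by genotype on the first principal component, which held 38.7% of the variance of the kept log2 signals. It set knockout 66, at a score of 55.9, apart from the others, which lay between -24.7 and 4.79. The second component, with 19.0%, had all knockout arrays at 10.8 or higher and all wild-type arrays at 0.95 or lower. Pearson correlations across probe sets, which are not independent replicates, were 0.928 to 0.940 between knockout 66 and the other arrays.

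**Figure D2:**
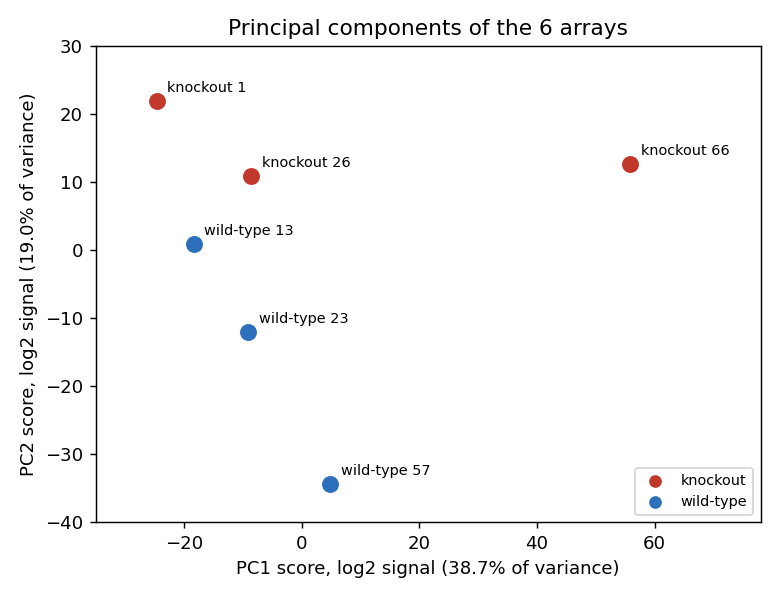
Scores of the 6 arrays on the first (38.7% of variance) and second (19.0%) principal components of log2 signal, knockout in red and wild-type in blue. Knockout 66 lies at 55.9 on the first component, and the other arrays at 4.79 or lower.

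Genes of the extracellular matrix were called lower as a group in the knockout, at the preset correlation alone. Of 28 measured members, 24 were below 0, the median log2 difference was -0.12, and camera gave an adjusted p of 0.000787. The correlation estimated within this list was 0.35, far above the preset 0.01, which treats genes as nearly independent. With the estimated correlation the adjusted p was 0.665 and the call was lost. The collagen genes Col1a1 (543 ± 65.7 against 777 ± 51.7, -0.51 ± 0.14) and Col1a2 (-0.35 ± 0.15), the matrix gene Postn (-0.68 ± 0.24) and the proteoglycan gene Lum (-0.61 ± 0.24) had the smallest p. No member passed on its own, over all genes or adjusted over the list alone. Markers of outflow tract, cushion and neural crest, which share 2 members with this list, also had lower mean deviations in knockout (-0.18 to -0.0076) than in wild-type (0.058 to 0.083), and the 3' to 5' ratios of actin and Gapdh were higher in all knockout arrays. The mean deviation of the matrix list from the average of the 6 arrays was -0.26 in knockout 1 and -0.17 in knockout 26, but 0.14 in knockout 66, above the 0.06 to 0.12 of the wild-type arrays. Without knockout 1 the median was -0.018 (adjusted p = 0.294). Without knockout 66 it was -0.27 (adjusted p = 1.53e-09), and Postn alone passed over all genes.

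Genes of oxidative metabolism, the respiratory chain and fatty acid oxidation were called lower as a group, by a small amount and at the preset correlation alone. Of 28 measured members, 23 were below 0, with a median of -0.073 and a camera adjusted p of 0.0211. The adjusted p was 0.665 with an estimated correlation. Cox8b, a respiratory chain subunit of heart and skeletal muscle, read 112 ± 33.5 against 200 ± 7.77 (-0.78 ± 0.25). The ATP synthase gene Atp5b gave -0.32 ± 0.14, and the fatty acid oxidation genes Hadhb and Acadvl -0.21 ± 0.10 and -0.28 ± 0.14. Without knockout 66 a second Hadhb probe set was the brighter one, at 0.12, and the first stood at -0.25. No member passed, over all genes or adjusted over the list alone. The call was lost without any one of knockout 1, knockout 26, wild-type 13 or wild-type 23, at medians of -0.074 to -0.047 and adjusted p from 0.124 to 0.213, the highest of the 18 alternatives, whose lowest was 8.78e-06. It was also lost with the stricter filter, with eBayes without a trend and without probe sets ending in _x_at or _s_at.

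Genes of the G1/S transition and DNA replication were called higher as a group, at the preset correlation alone. Of 23 measured members, 17 were above 0, with a median of 0.12 and a camera adjusted p of 0.0161. The adjusted p was 0.680 with the estimated correlation, 0.34 in this list against the preset 0.01. The replication clamp gene Pcna read 8087 ± 342 against 6877 ± 259 (0.23 ± 0.08), the origin licensing gene Cdc6 gave 0.45 ± 0.20, the cyclin gene Ccnd2 0.27 ± 0.12 and the ribonucleotide reductase gene Rrm2 0.25 ± 0.12. No member passed, over all genes or adjusted over the list alone. The list's mean deviation was 0.19 in knockout 1 and 0.07 in knockout 26, and -0.11 in knockout 66, below every wild-type array. The median was 0.17 without knockout 66 (adjusted p = 1.77e-05), and the call was lost without knockout 1 (median 0.063), knockout 26 (0.12), wild-type 23 (0.10) or wild-type 57 (0.061), at adjusted p from 0.0927 to 0.591. It was also lost without probe sets ending in _x_at or _s_at (0.071), with the mean of a gene's probe sets (0.073) and with eBayes without a trend. Genes of G2 and mitosis gave no call (24 measured, median 0.03, adjusted p = 0.302), except without knockout 66 (0.16, adjusted p = 0.0313). The median was 0.0029 without knockout 1 (adjusted p = 0.931, the highest of the 18 alternatives) and 0.0097 with the mean of a gene's probe sets. Members of that list went both ways: Aurkb, a mitotic kinase, gave 0.57 ± 0.17 and Cenpf, a kinetochore protein, -0.40 ± 0.12. Aurkb and Ccnd2 each had 1 other kept probe set just below 0.

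Genes of ribosomal proteins and translation were called higher as a group, at the preset correlation alone. Their median turned from 0.11 to -0.015 after quantile normalization. Of 19 measured members, 16 were above 0, and camera gave an adjusted p of 0.0161. It was 0.665 with the estimated correlation, 0.28 in this list against the preset 0.01. Rpl8 gave 0.25 ± 0.09. Eef1a1, the elongation factor of most tissues, gave 0.20 ± 0.09, but -0.11 after quantile normalization. Eef1a2, its muscle counterpart, was at -0.72 and was the one member that fell when adjusted over the list alone. The list's mean deviation was lowest in wild-type 57, at -0.12, and the call was lost without that array (median 0.061, adjusted p = 0.287), without knockout 1 (median 0.067, adjusted p = 0.288) or without knockout 26 (median 0.10, adjusted p = 0.0643), within a range of 0.00499 to 0.358 over the 18 alternatives. It was also lost with no filter, eBayes without a trend, array quality weights, no probe sets ending in _x_at or _s_at (median 0.080), the mean of a gene's probe sets (median 0.052) and quantile normalization. Among all probe sets, the median log2 difference was -0.04 in the dimmest of 10 equal groups and 0.05 in the brightest, and ribosomal genes are bright.

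Genes of the cardiac sarcomere gave no call, with 11 of 22 members on each side of 0, a median of -0.0058 and an adjusted p of 0.452. After quantile normalization, which gives all arrays the same distribution, the median was -0.12 (adjusted p = 1.7e-08), and without wild-type 57 it was -0.09 (adjusted p = 0.0283). It turned to 0.052 without knockout 1 (adjusted p = 0.953, the highest of the 18 alternatives). Myl2, the ventricular myosin light chain, read 22206 ± 2884 against 18772 ± 526 (0.23 ± 0.10, but -0.024 after quantile normalization). Myoz2 (-0.33 ± 0.15), Lmod2 (-0.30 ± 0.14) and Myom1 (-0.29 ± 0.14), which organise the Z-disc, thin filament and M-band, were on the other side. Genes of skeletal and smooth muscle gave a median of -0.01 over 11 measured members (adjusted p = 0.880), with smooth muscle actin, Acta2, at 0.27 ± 0.09.

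Genes of conduction and calcium handling had a median of -0.13, with 12 of 17 members below 0, and gave no call (adjusted p = 0.123). The median was -0.065 without wild-type 57, -0.079 without knockout 1 and -0.029 with array quality weights. Casq2, the calcium store protein of the cardiac sarcoplasmic reticulum, read 167 ± 38.1 against 295 ± 11.4 (-0.79 ± 0.20) and fell when adjusted over the list alone, and the potassium channel subunit gene Kcne1 gave -0.65 ± 0.27. Without knockout 66 the list was called, at a median of -0.09 (adjusted p = 0.0374, the lowest of the 18 alternatives, whose highest was 0.591), and so it was with the stricter filter (-0.13, adjusted p = 0.0483). The natriuretic and wall stress genes gave a median of -0.08 over 11 members (adjusted p = 0.123), with the LIM protein gene Fhl2 at -0.27 ± 0.11. Quantile normalization (-0.13, adjusted p = 0.00071) or leaving out wild-type 57 (-0.15, adjusted p = 0.000363) brought this list past the threshold, within a range up to 0.625 over the 18 alternatives, reached without wild-type 13 at a median of -0.0037.

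Cardiac transcription factors gave a median of -0.06 over 27 measured members (adjusted p = 0.245). Isl1, a factor of cardiac progenitors, was at -0.90 ± 0.43, from signals of 129 ± 85.3 and 227 ± 69.7. The log2 difference of Isl1 was -0.37 without knockout 66. Myocd, a coactivator of muscle genes, was at -0.25 ± 0.16. Genes of trabeculation signalling gave -0.08 over 14 members (adjusted p = 0.245), or -0.035 without wild-type 13 and -0.040 without knockout 1, with the matrix protease gene Adamts1 at -0.39 ± 0.19. Growth factor signalling through TGF-beta, BMP and Wnt gave -0.07 over 24 members (adjusted p = 0.452), with the Wnt antagonist Sfrp1 at -0.37 ± 0.14.

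Lists of hypoxia, stress responses and cell cycle inhibitors gave no call. Hypoxia and glycolysis genes had a median of 0.07 over 26 members (adjusted p = 0.123), with the mitophagy gene Bnip3 at 3566 ± 113 against 2876 ± 72.2 (0.31 ± 0.09). The list was called with array quality weights and without knockout 66 (0.11, adjusted p = 0.0244), within a range of 0.0129 to 0.639 over the 18 alternatives. The median was 0.0086 without knockout 26, 0.031 without wild-type 57, 0.029 after quantile normalization and 0.0056 with the mean of a gene's probe sets. Genes of the unfolded protein and integrated stress responses had a median of -0.05 while camera pointed up (adjusted p = 0.823), and the endoplasmic reticulum chaperone gene Hspa5 stood at 10784 ± 1468 against 8040 ± 715 (0.42 ± 0.11), while its other 2 kept probe sets were just below 0. Heat shock proteins and myosin chaperones had a median of 0.03 (adjusted p = 0.750), with the mitochondrial chaperonin gene Hspd1 at 0.19 ± 0.08. Inhibitors of the cell cycle and targets of p53 had a median of -0.03 (adjusted p = 0.744), or -0.091 without knockout 66 and -0.090 with the mean of a gene's probe sets, with Perp at -0.48 ± 0.17.

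Markers of other cell types and neighbouring tissues gave no call. Epicardial markers had a median of 0.05 over 14 members (adjusted p = 0.210). Krt8 rose when adjusted over this list alone, and also over the foregut and pharynx list, which shares it. Wt1, a transcription factor of the epicardium, gave 0.30 ± 0.18 and Aldh1a1 1.07 ± 0.53, or 0.25 without wild-type 13, and without knockout 66 the list was called (0.17, adjusted p = 0.0263, the lowest of the 18 alternatives, whose highest was 0.591). Markers of outflow tract, cushion and neural crest had a median of -0.13 over 17 members (adjusted p = 0.210), with the mesenchymal transcription factor gene Snai2 at -0.76 ± 0.24 and the mural cell receptor gene Pdgfrb at -0.47 ± 0.17. That list was called without knockout 66 (-0.12, adjusted p = 0.0313, the lowest of the 18 alternatives, whose highest was 0.894) and under the stricter filter. The median turned to 0.027 without knockout 1, and was -0.053 without wild-type 57 and -0.022 without a filter. Postn belongs to both this list and the matrix list. Ppbp fell when adjusted over the macrophage and platelet list alone (median -0.06, adjusted p = 0.210).

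The remaining lists stood close to 0 or went both ways. Medians were -0.04 for erythroid markers (adjusted p = 0.823), 0.03 for endothelium and endocardium (0.913), 0.0015 for atrium (0.750), 0.11 for liver and gut (0.911), 0.0052 for foregut and pharynx (0.864) and 0.06 for the nervous system (0.979). The embryonic globin gene Hbb-y stood at 0.26 ± 0.10, which became -0.024 after quantile normalization. The mean deviation of the erythroid list ran from 0.49 in knockout 1 to -0.32 in knockout 66. The list of Naca, Smyd1 and the Naca relatives Btf3 and Btf3l4 had too few measured members for a test. Btf3l4 stood at -0.11 and Btf3 at -0.08, while the other 2 kept Btf3 probe sets were at 0.05 and 0.08. Of the 25 lists, 4 were called at the preset correlation, 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.698, or 0.0864 in either direction). At the preset correlation, 5 of the 10 splits of the 6 arrays into 3 and 3, the real one among them, called at least 4 lists. In the endothelial and the liver and gut lists the median was above 0 while camera pointed down, and in the erythroid list the reverse held.

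**Figure D3:**
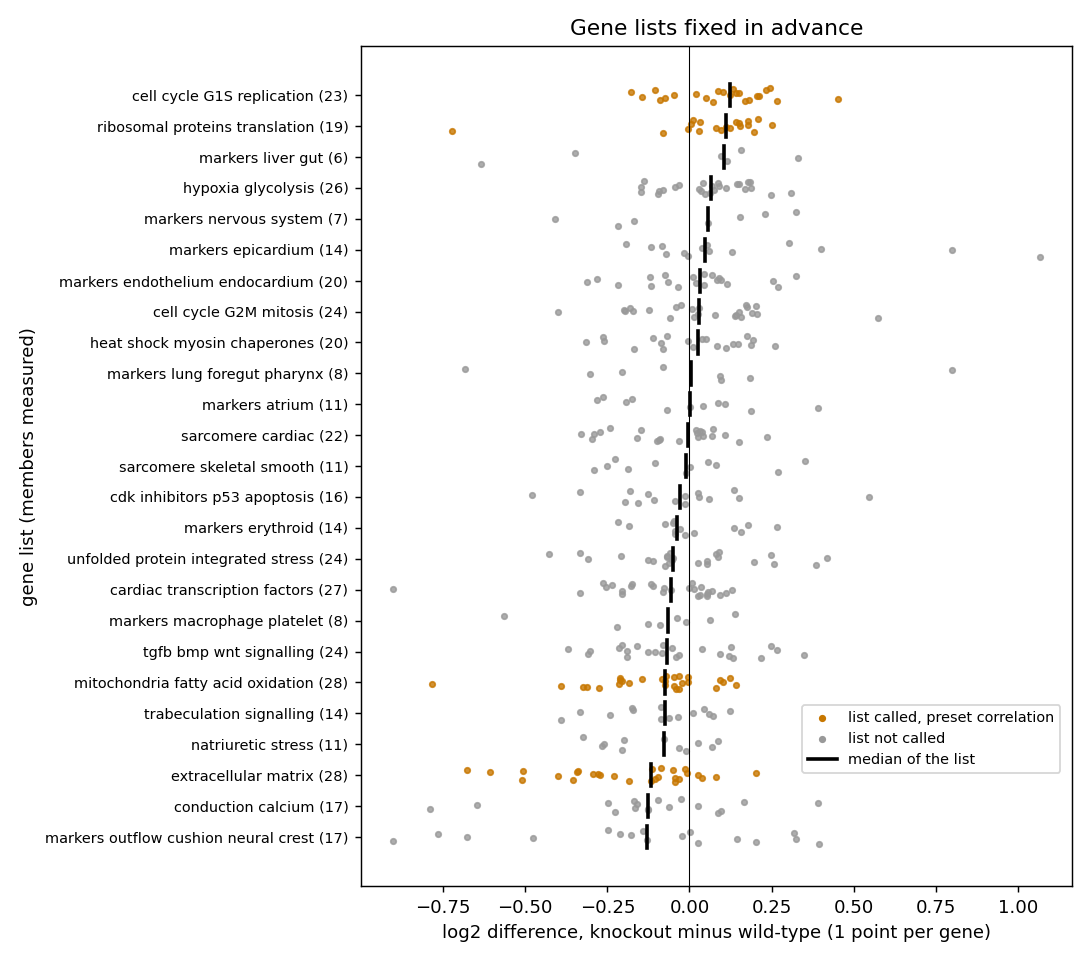
Log2 difference (knockout minus wild-type) of each measured gene, 1 point per gene, in the 25 tested lists ordered by median, with the number of measured members in brackets and a black bar at the median. Lists called by camera at the preset correlation are orange. Matrix (median -0.12) and oxidative genes (-0.073) lie mostly left of 0, and G1/S (0.12) and ribosomal genes (0.11, but -0.015 after quantile normalization) mostly right.

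Control transcripts and sex-linked genes also differed between arrays. The 3' to 5' signal ratio of the actin control probe sets, which rises as the labelled RNA gets shorter, was 2.54 ± 0.05 in knockout and 2.14 ± 0.10 in wild-type, without overlap. That of Gapdh was 1.35 ± 0.09 against 1.17 ± 0.04, again without overlap. For both, the two-sided exact permutation p was 0.1, the smallest the design allows. In each of the 4 called lists, at least 1 knockout array had a mean deviation within the wild-type range or beyond its far end. The ratio for 18S ribosomal RNA was 1.46 ± 0.47 against 1.44 ± 0.11.

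Xist, the RNA of the inactive X chromosome, read 6275 to 7481 in 5 arrays and 466 in wild-type 57, while the Y-linked genes Eif2s3y, Kdm5d and Uty read 638, 409 and 400 in wild-type 57. In knockout 26 and wild-type 13 and 23 these Y-linked signals were 2.10 to 93.5. Knockout 1 had 167, 208 and 153, and knockout 66 had 213, 295 and 151, between those levels. Without genes on chromosomes X and Y, a setting added after these signals were seen, the 4 called lists and the 0 calls over genes were the same. That setting leaves in place any effect of sex on genes of other chromosomes. Since the array of male type was a wild-type one, such an effect cannot be separated from genotype here.

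**Figure D4:**
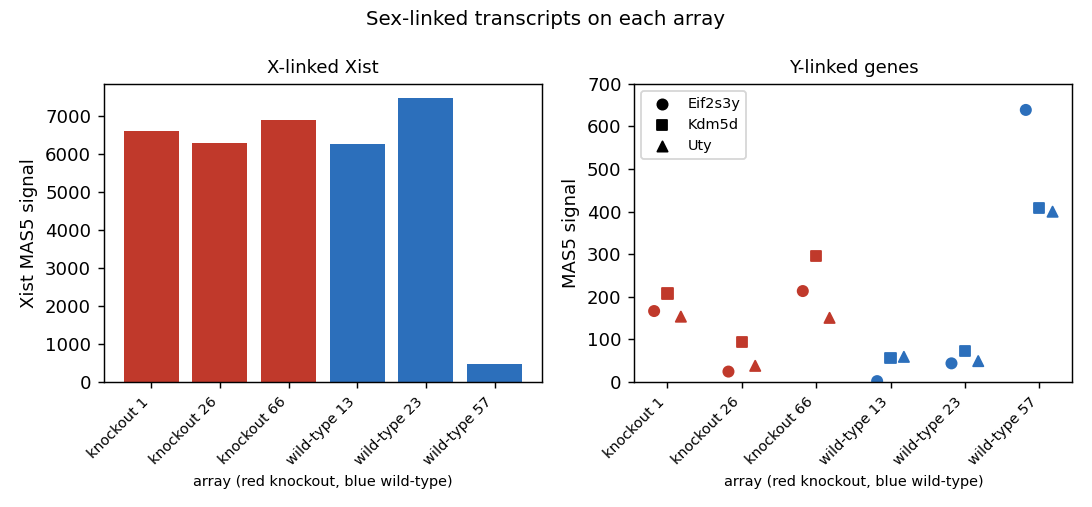
MAS5 signal of X-linked Xist (left, bars from 0) and of the Y-linked genes Eif2s3y, Kdm5d and Uty (right, points) on each array, with 1 probe set per gene, knockout in red and wild-type in blue. Xist is low (466) in wild-type 57 alone, and Y-linked signals are highest there and intermediate in knockout 1 and knockout 66.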

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

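The tests of what set knockout 66 apart were chosen after its position was seen, and the ratios of control transcripts were compared without a prior plan. In the actin control probe sets, which lie outside the gene comparisons, the 3' to 5' signal ratio stood higher in knockout, at 2.54 against 2.14 in wild-type, with an exact permutation p of 0.1, the smallest that 3 arrays against 3 can give. The same ratio for Gapdh was 1.35 in knockout and 1.17 in wild-type, with the same exact p of 0.1.

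Knockout 66 stood apart from the other 5 arrays on the first principal component, and without it camera called 9 lists, against 4 with all arrays. Measurement noise on that array stays open. Noise that is independent between probe sets adds nothing to the covariance between 2 probe sets of 1 gene, but shared error does. That covariance was 0.0124 (95% interval 0.0067 to 0.0179, resampling 3679 genes), against at most 0.0102 on the other arrays. The variance was 0.178 against at most 0.093. The correlation of the 2 probe sets was 0.073, within the 0.030 to 0.123 of the other arrays. Lower RNA integrity may also contribute and stays open, since 2 of 3 control ratios were highest in knockout 66 (Gapdh at 1.45 and 18S at 1.96), while its actin ratio of 2.56 lay just below the 2.57 of knockout 1. A difference between embryos or litters is untested, because the labels give neither for any array.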

How the results depend on the processing

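The alternative without genes on chromosomes X and Y was chosen after the sex-linked signals were seen, and all others before the data were examined. Where a value changed its sign or its side of the threshold, the cause was not tested, except that Fen1, Cdca8 and Rps24 (without probe sets ending in _x_at or _s_at), Hadhb (without knockout 66) and Btf3 (without knockout 1 or wild-type 13) were then read from another probe set. On its first probe set, Hadhb stayed at -0.25 and Btf3 was at -0.24 and 0.018.

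The count of 0 probe sets changed in knockout and 0 genes changed in knockout in limma held in all alternatives except 3. With array quality weights, which gave 2692 probe sets at an unadjusted p under 0.05 against 1083, 6 probe sets and 8 genes passed. Leaving out single arrays gave 0 to 2 probe sets and 0 to 2 genes: 2 of each without knockout 1 (Igdcc4 and Nudt6, both lower in knockout and named after their values were seen) and 1 gene, Postn, without knockout 66. The number of lists called, 4 at the preset correlation, became 1 with eBayes without a trend, 1 without probe sets ending in _x_at or _s_at, 2 with the mean of a gene's probe sets, 0 with an estimated correlation and 0 with fry. Leaving out single arrays gave 0 (without knockout 1) to 9 (without knockout 66), with 1 without knockout 26 and 2 without wild-type 23, from fewer arrays in each fit. Over 18 alternatives at the preset correlation, the matrix list was called in 17, G1/S and oxidative metabolism in 11 each and the ribosomal list in 9. The adjusted p ranged from 1.53e-09 to 0.294 for matrix, 1.77e-05 to 0.591 for G1/S, 8.78e-06 to 0.213 for oxidative metabolism and 0.00499 to 0.358 for ribosomal genes.

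The matrix, oxidative and G1/S medians kept their sign in all 18. Apart from single arrays left out, 257 list medians kept their sign and side, 23 reversed, 5 became calls and 11 lost theirs. Of named gene values, 1398 kept sign and side, 17 reversed and 8 became calls. Quantile normalization turned the medians of ribosomal genes (-0.015), heat shock proteins (-0.0099) and atrium (-0.077), and the differences of Naca (-0.015), Myl2 (-0.024), Eef1a1 (-0.11), Hbb-y (-0.024), Hbb-bh1 (-0.016) and Myl7 (-0.045). Centring on array medians turned the cardiac sarcomere (0.0082) and skeletal and smooth muscle (0.0036). With array quality weights, skeletal and smooth muscle (0.016), erythroid (0.0067), liver and gut (-0.15), foregut (-0.10) and nervous system (-0.10) turned, as did the log2 difference of Btf3l4 (0.014) and those of Rbp4 (-0.092) and Pax6 (-0.0086). Without a filter, skeletal and smooth muscle (0.0015), atrium (-0.045), macrophage and platelet (0.025) and nervous system (-0.012) turned, and with the stricter filter cardiac transcription factors (0.0032) and endothelium (-0.033). A pseudocount of 1 turned foregut (-0.015). Without probe sets ending in _x_at or _s_at, heat shock proteins (-0.036), foregut (-0.081), Fen1 (0.30), Cdca8 (-0.099) and Rps24 (-0.56) turned. With the mean of a gene's probe sets, skeletal and smooth muscle (0.0015), unfolded protein response (0.016), heat shock proteins (-0.047), atrium (-0.068), Pln (-0.019), Hk1 (-0.15), Rps24 (-0.097), Btf3 (0.017) and Eng (0.023) turned.

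Leaving out single arrays, 101 list medians kept sign and side, 30 reversed, 7 became calls and 12 lost theirs, and of named gene values 703 kept both, 15 reversed and 1 became a call. The medians that crossed 0 ranged from -0.091 to 0.052 for the cardiac sarcomere, -0.15 to 0.013 for skeletal and smooth muscle, -0.080 to 0.0023 for cardiac transcription factors, -0.050 to 0.038 for the unfolded protein response, -0.039 to 0.10 for heat shock proteins and -0.11 to 0.024 for TGF-beta, BMP and Wnt. Among markers they ranged from -0.24 to 0.16 for erythroid cells, -0.027 to 0.077 for endothelium, -0.095 to 0.091 for atrium, -0.16 to 0.027 for outflow tract, -0.14 to 0.21 for liver and gut, -0.077 to 0.14 for foregut, -0.20 to 0.036 for macrophages and platelets and -0.13 to 0.16 for the nervous system. The genes that crossed 0 were Smyd1 (-0.25 to 0.011), Hadhb (-0.24 to 0.12), Btf3l4 (-0.23 to 0.11), Btf3 (-0.18 to 0.091), Hbb-bh1 (-0.0076 to 0.26), Hemgn (-0.46 to 0.037), Tbx5 (-0.49 to 0.0074), Hnf4a (-0.54 to 0.012), Rbp4 (-0.0088 to 0.38), Gp1bb (-0.27 to 0.072), Dcx (-0.57 to 0.16), Xist (-0.054 to 1.93) and Uty (-0.62 to 0.41).

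No setting moved the median of all probe sets by 0.1. Liver and gut gave values under 16 alternatives, and the macrophage and nervous system lists under 17, because some settings left fewer than 5 members. Signal over background limits the dim genes, whose differences the added 16 shrinks, and the number of arrays limits the rest.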

Other observations

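The ranks among random lists, the counts over other splits and the tests of the cell share, of both-sex RNA and of a complete Y chromosome were chosen after the results they bear on were seen. The test of a further heart list and that of dim probe sets were written before.

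Several lists that gave no call ranked low among 10000 random lists of the same size and matched signal. The median of conduction and calcium handling lay at percentile 0.26, that of natriuretic and wall stress genes at 0.84, that of outflow tract, cushion and neural crest at 2.18, that of the cardiac sarcomere at 2.74 and that of the unfolded protein response at 3.75. For the cardiac sarcomere the random lists had a median of 0.05. Matrix genes lay at 0.03 and oxidative genes at 0.06, G1/S genes at 99.8, and ribosomal genes, which camera had called, at 91.6. The genes of an array are not independent, so these ranks are not p-values.

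A further list of 32 genes of the maturing heart, 26 of them measured, added genes outside the rule for naming, picked after their values were seen. Txlnb, a syntaxin-binding protein of muscle, read 234 in knockout and 337 in wild-type (-0.50 ± 0.17), Fsd2 592 and 780 (-0.38 ± 0.15), the splicing factor gene Rbm20 772 and 963 (-0.31 ± 0.13) and the sarcoglycan gene Sgca 149 and 224 (-0.54 ± 0.22). Mlycd, a malonyl-CoA decarboxylase, went the other way, at 191 and 115 (0.67 ± 0.23). These 5 had an unadjusted p under 0.05 in limma, and 0 genes passed over all genes.

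Mb, Kcnk3, Casq2, Eef1a2, Cox8b and Kcne1, picked as muscle genes after their values were seen, had lower values in knockout, by -1.30 to -0.65, though none passed over all genes and the second Mb probe set stood at 0.80. Kcne1, the smallest of these, was at -0.32 without knockout 26, and Mb at -0.25 with the mean of its probe sets. A smaller share of cardiomyocytes would lower sarcomere genes alike. Their list had a median of -0.0058 (95% interval -0.13 to 0.037), or -0.12 after quantile normalization. The sarcomere list thus did not fall as far as these genes. The genes compared were picked for low values after these were seen, so a sarcomere median above theirs was likely in advance. That median also depended on the scaling. The comparison therefore cannot decide on a smaller share of cardiomyocytes, which is not excluded. A lower level of genes of the maturing heart may contribute but stays open. The further list had a median of -0.057 (95% interval -0.12 to 0.00084), with 17 of 26 members below 0. Its camera p was 0.0621 in limma, or 0.210 with an estimated correlation. The intervals of both lists come from resampling their genes, so they do not measure the spread between samples. Genotype is the one difference the labels give, and the embryos may also have differed in stage or litter, which the labels do not give. Sex-linked signals were not balanced either: Xist was low in wild-type 57 alone (466) and 6295 or higher in every knockout array. An effect of sex on these genes was not tested. The 3' to 5' ratios of actin (2.54 in knockout, 2.14 in wild-type) and Gapdh (1.35 and 1.17) also did not overlap between genotypes. Whether RNA length bears on the lower muscle genes was not tested.

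Knockout 1 and knockout 66 had Y-linked signals of 31.3% and 42.0% of the level in wild-type 57, the one array of male type, together with Xist at 108% and 95.8% of the mean of knockout 26, wild-type 13 and wild-type 23. A raised signal of dim probe sets is argued against. On either array at most 0.01% of 10000 random sets of like level rose as much, the lowest bound that this many draws can give. RNA of both sexes would keep the Xist and Y shares at a sum of 100%. The sums were 139% in knockout 1 (95% interval over probe sets 115 to 164) and 138% in knockout 66 (94.7 to 181). The first interval lies above 100% and the second includes it, and RNA of both sexes stays open. A single embryo with a complete Y chromosome and 2 X chromosomes, which would give a Y share near 100%, stays open at 42.0%, the higher of both. With 1 male array the spread of the male level between embryos is unknown, so these shares exclude neither, and no other biological explanation was tested.

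The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 0 probe sets and 0 genes, and the highest of the others 1 probe set and 0 genes. No split can give fewer than 0, so that all 10 reach the real count carries no information. For lists, 5 of 10 splits called at least the real 4, and the highest other called 5. At an unadjusted p under 0.05, 4 of 10 splits gave at least the real 1083 probe sets. The highest other gave 2144, with knockout 1, knockout 26 and wild-type 13 against the rest, and 1994 came from knockout 1, wild-type 13 and wild-type 23 against the rest.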
